A study of Mus musculus with 12 samples.

How the data were processed

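The libraries were made, per the labels' protocols, from total RNA of sciatic nerve fragments, extracted with Trizol and a column, treated with DNase, depleted of ribosomal RNA and prepared with a directional kit and 15 PCR cycles. The submitters' processing notes name CASAVA 1.8.2, cutadapt 1.2.1, DESeq2 (version not given) and the mouse genome build mm10. The aligner, the counting tool and the treatment of reads matching several genes are not given in the sources used here. The deposited values are read here as estimated counts: whole numbers, not scaled to library size, in 1 table of 30452 genes by 12 libraries. They were used without rounding. For short genes they are not plain fragment counts. Among 227 genes with a longest transcript of at most 120 bases, the smallest of 957 values above 0 is 19 and none is under 10, whereas 25.8% of the values above 0 are under 10 for genes of 500 to 1000 bases. In 58 T-cell receptor alpha J segments the lowest values cluster at medians of 82 to 163.5 in all libraries but CTL bridge 2, with the next values at 147 to 285. In CTL bridge 2 a lone segment stands at 49 and the next value is 111. The test had been chosen for raw counts before the data were examined, and edgeR was kept because genes up to 120 bases hold 0.243% of the counts and 2, 2, 1, 12 and 0 of the calls in the 5 comparisons. Small values are also rare between 120 and 200 bases (1.04% under 10) and between 200 and 300 (0.775%), classes that hold a further 0.176% and 1.80% of the counts. Receptor segments that the naming rule picked are not described, and levels of other short genes, histones included, carry the same caution.

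The lowest and highest library total of each group are given in the report, and the remaining library had 28559970 in CTL bridge, 32612435 in Nf1 KO bridge, 32803800 in CTL distal stump and 36027933 in Nf1 KO distal stump. With 3 counts as a floor, a library resolves 0.0770 to 0.159 CPM. In all, 5433 genes had no count in any library, 19189 genes passed edgeR's filterByExpr by group and 11263 did not, and the tested genes hold 99.96% of the counts. All columns were mapped to samples. The non-coding gene Gm15662 took 24.5% of the counts in Nf1 KO distal 1, whose TMM factor was 0.763, and 9.00% and 6.57% in CTL distal 1 and Nf1 KO distal 3. Of 30452 gene IDs, 30123 were found in GENCODE M21 (GRCm38, the assembly of mm10) and 29638 symbols were equal. Coordinates come from that annotation. The counts of 131 tested genes equal those of another gene.

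Groups come from the labels: genotype by region, 3 samples each. A single model with 1 coefficient per group was fitted to all 12 libraries with edgeR 4.0.16 (TMM factors, glmQLFit, glmQLFTest, Benjamini-Hochberg adjustment at 0.05) in R 4.3.3. The contrasts were Nf1 KO against CTL in each region, bridge against distal stump in each genotype, and the interaction of genotype and region. Nf1 was also tested with an exact permutation test on log2 CPM. Gene lists fixed beforehand, 31 lists with 490 genes, were tested with camera of limma 3.58.1 on log CPM with a preset correlation of 0.01, adjusted over the lists, where at least 3 members were measured. Camera with a correlation estimated from the data and fry were run beside it. DESeq2 1.42.0 and limma-voom served as other tests.

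Named genes followed a rule: Nf1, then, among genes with adjusted p under 0.05, a mean log2 CPM of at least 1, a gene symbol other than a placeholder and no overlap of the groups' libraries, the 10 largest rises and 10 largest falls. To these came up to 4 members with the smallest p of each list that was called or had at least 2 called members, and the most abundant member of the skeletal muscle, adipocyte, erythroid, keratinocyte and neuronal lists. Where no gene passed, the 5 smallest p per direction were taken. The report describes mainly those whose call held under DESeq2, other size factors, the replicate block and each library left out. Mki67, Gm8797, Gm20474 and the Nlrp1 genes were chosen after their values were seen. S100a8, Adipoq, Acta1 and Hbb-bs serve as markers of tissue composition. Some genes that the rule names are not reported here.

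The procedure was tested on simulated counts drawn for the 19189 genes, with 68, 66 and 66 genes changed by log2 0.5, 1 and 2. The share recovered with the right sign was 23.5, 53.0 and 72.7% for genotype in the bridge, 26.5, 71.2 and 75.8% for genotype in the distal stump, 22.1, 51.5 and 75.8% for region in CTL, 22.1, 47.0 and 69.7% for region in Nf1 KO, and 7.35, 31.8 and 75.8% for the interaction. A first requirement of 70% recovery at log2 2 was missed by region in Nf1 KO and was replaced by one on bias and false calls. For the 4 group comparisons the largest gap between recovered and simulated median was then 0.0616 log2 units, and false calls were at most 5.47%. The new requirement was not applied to the interaction, whose 11.6% of false calls (10 of 86 calls) would have missed it. In the interaction a simulated change of log2 0.5 came back at a median of 0.575. None of 30 unchanged lists was called. The genes were drawn independently of each other, so this does not show how the list test behaves where members are correlated.

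Alternatives were upper-quartile and RLE size factors, other tests, no filter and a filter of 1 CPM in 3 libraries, a fit of the compared groups alone, a replicate block, a test against a log2 change of 0.5, a robust fit, and each library left out. Alternatives added after the data were seen were covariates for Y-linked and muscle transcripts, CTL bridge 1 and 3 left out together, protein-coding genes alone, repeated genes counted once, genes of at least 500 bases, and pairs nested in genotype. Splits of the libraries into other groups of equal size were also counted. Raw reads were not used here.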

Results

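RNA was sequenced from mouse sciatic nerves 14 days after injury. At that time regenerating tissue called the bridge joins the nerve ends, and the nerve beyond it is the distal stump, in which cut axons have degenerated. Control mice (CTL, P0-CreERT2:YFPfl/fl:Nf1+/+) were compared with Nf1 KO mice (P0-CreERT2:YFPfl/fl:Nf1fl/fl), in which tamoxifen removes Nf1 from myelinating Schwann cells. Nf1 encodes neurofibromin, a GTPase-activating protein that switches RAS off. The study asks which signals of the injured nerve's surroundings could favour or oppose tumour formation by cells that have lost Nf1. Each sample pooled 6 nerve fragments of 0.5 mm from multiple mice, and there were 3 samples for each of the 4 combinations of region and genotype, 12 libraries in all. Totals per library ran from 18821445 to 35871914 in CTL bridge, 26124609 to 33887873 in Nf1 KO bridge, 28852593 to 35653461 in CTL distal stump and 29597833 to 38981819 in Nf1 KO distal stump. Of 30452 genes listed, 19189 were abundant enough to test. Levels are given in CPM (counts scaled to a common library size) as mean ± SD of 3 libraries, and changes as log2 fold changes with a standard error (SE) and edgeR's adjusted p. The SE was derived from edgeR's test, as the size of the log2 fold change divided by the square root of the test's F statistic.

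Nf1 itself (chromosome 11, 79339693 to 79581612) was measured first in every library. It stood at 62.5, 67.4 and 60.1 CPM in the CTL bridge libraries 1 to 3 and at 42.4, 54.7 and 46.4 CPM in the Nf1 KO bridge libraries. In the distal stump it stood at 69.7, 57.0 and 67.3 CPM in CTL and at 42.5, 43.1 and 42.3 CPM in Nf1 KO. Every Nf1 KO library was therefore below every CTL library of its region. The bridge level was 75.6% of CTL (log2 fold change −0.40, SE 0.10, adjusted p = 0.0218) and the distal level 65.9% (−0.60, SE 0.10, adjusted p = 0.0056). An exact two-sided permutation test gave p = 0.1 in each region, the smallest value 3 libraries against 3 can reach. The bridge call was lost when any 1 of 4 libraries was left out: the adjusted p was 0.0553 without CTL bridge 1, 0.0742 without CTL bridge 2, 0.0778 without Nf1 KO bridge 1 and 0.0677 without Nf1 KO bridge 3. It was 0.0541 when the bridge libraries alone were fitted. Only recombined cells lose Nf1, and counts over the whole gene include exons outside the deleted part.

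The first comparison asks how the bridge changes when Schwann cells lose Nf1. Y-linked genes were lower in Nf1 KO, with a mean log2 CPM of 4.25 against 5.16 in CTL. The genotype effects of both regions are therefore not separated from a possible difference in the sex of the pooled mice. Among the largest rises were those of Prkg2, a cGMP-dependent protein kinase, and Corin, a protease that activates natriuretic peptides. Prkg2 (chromosome 5, 98929773 to 99037351) rose from 1.13 ± 0.191 to 10.2 ± 1.08 CPM (log2 fold change 3.17, SE 0.15, adjusted p = 8.0e-06), and Corin (chromosome 5, 72300025 to 72504473) from 4.21 ± 1.08 to 19.4 ± 0.458 CPM (2.20, SE 0.16, adjusted p = 7.4e-05). Add2, a cytoskeletal adducin (chromosome 6, 86028681 to 86124409), rose by 2.89 (SE 0.41), Ajap1 (chromosome 4, 153373221 to 153482811) by 2.45 (SE 0.32) and the protease-activated receptor gene F2rl1 by 2.25 (SE 0.40). Inmt, which encodes an N-methyltransferase (chromosome 6, 55170626 to 55175043), fell from 27.5 ± 2.05 to 4.70 ± 0.59 CPM (−2.55, SE 0.15, adjusted p = 2.7e-05). The transcription factor gene Olig1 (−2.59, SE 0.47), the proton pump subunit gene Atp6v0d2 (−2.21, SE 0.31), the melanin synthesis gene Tyrp1 (−1.99, SE 0.41) and BC035947 (−1.90, SE 0.27) also fell. In all, 2795 genes passed the test, 1498 higher and 1297 lower in Nf1 KO, and 418 of them changed at least 2-fold.

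Cell cycle genes rose as a group in the Nf1 KO bridge. All 22 measured members of the proliferation list rose, and 22 also passed adjusted over the list alone, with a median log2 fold change of 0.84. The cyclin genes Ccnb2 (1.09, SE 0.11) and Ccna2 (0.93, SE 0.08), the ribonucleotide reductase gene Rrm2 (0.92, SE 0.07) and the mitotic kinesin gene Kif20a (0.77, SE 0.08) had the smallest p. Mki67, a marker of cycling cells named after its values were seen (chromosome 7, 135689784 to 135716361), rose from 18.4 ± 1.82 to 37.6 ± 1.13 CPM (1.03, SE 0.14, adjusted p = 0.0015). In the distal stump Mki67 was not called (0.27, edgeR adjusted p = 0.287). It was called there without CTL distal 1 (0.46, edgeR adjusted p = 0.0421), but not when any other distal library was left out. The list's camera test gave an adjusted p of 3.4e-21, against an adjusted p = 0.0578 with an estimated correlation.

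Feedback regulators of RAS/ERK signalling rose too: 9 of 20 members rose, none fell, and 11 passed adjusted over the list alone (camera adjusted p = 5.7e-07, and adjusted p = 0.0578 with an estimated correlation). They included the pathway inhibitors Spry4 (1.05, SE 0.10) and Spred1 (0.61, SE 0.05), the ERK phosphatase gene Dusp6 (0.43, SE 0.07) and the ERK-induced transcription factor gene Etv5 (0.43, SE 0.07). In the TGF-beta list 9 of 21 members rose and 1 fell (16 adjusted over the list alone, camera adjusted p = 2.7e-05, and adjusted p = 0.0578 with an estimated correlation). The target gene Ctgf (1.63, SE 0.26), the receptor gene Tgfbr2 (0.47, SE 0.07) and Skil (0.89, SE 0.05), whose product restrains SMAD signalling, were among those that rose. Matrix genes followed: 17 of 22 rose and 1 fell (19 adjusted over the list alone, camera adjusted p = 7.6e-11, and adjusted p = 0.259 with an estimated correlation). Postn, a matrix protein of healing tissue, rose from 1778 ± 112 to 3958 ± 416 CPM (1.15, SE 0.16), Col12a1 from 57.4 ± 4.30 to 138 ± 6.41 CPM (1.27, SE 0.13), and Bgn (0.88, SE 0.10) and Col1a1 (0.77, SE 0.10) less.

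Immune genes moved in several lists. Of 13 MHC class II and dendritic cell genes, 6 rose and none fell (10 adjusted over the list alone, camera adjusted p = 2.6e-06, and adjusted p = 0.311 with an estimated correlation). Among them were the cytokine receptor gene Flt3 (1.54, SE 0.20), Cd209a (1.14, SE 0.18) and Clec9a (0.57, SE 0.11). Of 26 chemokines and cytokines, 7 rose and 2 fell (10 adjusted over the list alone, camera adjusted p = 0.0158, and adjusted p = 0.553 with an estimated correlation). Il1b (2.04, SE 0.42), Cxcl14 (1.28, SE 0.10) and the alarmin Il33 (0.59, SE 0.06) rose, while Il34, a ligand of the CSF1 receptor, fell (−0.47, SE 0.08). Of 20 interferon-stimulated genes 5 rose (10 adjusted over the list alone), with Isg15 at 0.75 (SE 0.12), and the camera adjusted p was 0.0031, against an adjusted p = 0.615 with an estimated correlation. Immediate early and stress genes rose in 4 of 12 cases, Ier2 by 0.96 (SE 0.17), with 6 adjusted over the list alone (camera adjusted p = 7.0e-04, and adjusted p = 0.311 with an estimated correlation). Without CTL bridge 2 the chemokine list had an adjusted p of 0.0718 and the interferon list 0.0565, and without Nf1 KO bridge 1 the chemokine list had 0.0723. The neutrophil marker S100a8 stood at 592, 17.0 and 15.9 CPM in Nf1 KO bridge libraries 1 to 3 and at 14.7 ± 7.17 CPM in CTL, and none of 12 neutrophil genes was called (list adjusted p = 0.207). The neutrophil list had a mean log2 CPM of 4.76 in Nf1 KO bridge 1, against 1.42 and 1.16 in the other Nf1 KO bridge libraries, and of 4.01 in Nf1 KO distal 1.

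Myelin genes fell in the Nf1 KO bridge. Of 20 members, 15 fell and none rose (18 adjusted over the list alone), with a median of −0.84, a camera adjusted p of 7.6e-11 and an adjusted p = 0.341 with an estimated correlation. The membrane protein gene Mal (−1.03, SE 0.18), the Schwann cell claudin gene Cldn19 (−0.98, SE 0.13) and Cnp (−0.83, SE 0.14) fell. Perineurial markers fell in 7 of 11 cases and rose in none (8 adjusted over the list alone, camera adjusted p = 2.6e-06, and adjusted p = 0.0578 with an estimated correlation): Lypd2 (−1.28, SE 0.12), Krt19 (−1.03, SE 0.14), Msln (−1.01, SE 0.12) and the netrin gene Ntn4 (−0.92, SE 0.12). Adipocyte genes fell in 10 of 12 cases (11 adjusted over the list alone, camera adjusted p = 5.7e-07, and adjusted p = 0.341 with an estimated correlation). Among them were Acvr1c (−1.44, SE 0.32) and the lipase gene Lpl (−0.71, SE 0.09), and the fat marker Adipoq stood at 77.3 ± 22.0 CPM in CTL and 33.3 ± 14.9 in Nf1 KO. Cholesterol synthesis genes fell in 5 of 18 cases (6 adjusted over the list alone, median −0.37, camera adjusted p = 0.0010, and adjusted p = 0.602 with an estimated correlation).

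Further lists were called with few or no called members. The neuronal and axonal list had 1 of 9 members lower (2 adjusted over the list alone, camera adjusted p = 0.0144, and adjusted p = 0.341 with an estimated correlation). None of 6 erythroid genes was called (5 adjusted over the list alone, camera adjusted p = 0.0117, and adjusted p = 0.553 with an estimated correlation), and the globin gene Hbb-bs stood at 1260.4 ± 559 CPM in CTL and 462 ± 46.8 in Nf1 KO. None of 16 skeletal muscle genes was called (0 adjusted over the list alone, camera adjusted p = 0.0209, and adjusted p = 0.703 with an estimated correlation), and Acta1 stood at 1220.0 ± 818 CPM in CTL and 316 ± 165 in Nf1 KO. The erythroid list's adjusted p was 0.0667 without CTL bridge 3, and the muscle list's was 0.105 without CTL bridge 1, 0.0840 without CTL bridge 3 and 0.0921 without Nf1 KO bridge 2. Without both muscle-rich libraries the erythroid list had 0.281 and the muscle list 0.573, and with a Y-linked covariate they had 0.0596 and 0.322. Under fry, in place of camera, the cholesterol synthesis and interferon lists each had 0.105, the erythroid list 0.0822 and the muscle list 0.318.

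Schwann cell, fibroblast and several other lists had members in both directions, and camera called none of the following lists as a group in the bridge. Fry called some lists that camera did not. Among Schwann lineage markers 2 rose and 4 fell, Kcna1 at −0.54 (SE 0.12), and among repair Schwann cell genes 5 rose and 4 fell, the adhesion molecule gene Ncam1 by 0.70 (SE 0.10), with adjusted p = 0.180 and 0.660. The repair list's median (−0.04) and its test, which pointed up, differ in sign. Fibroblast markers rose in 2 and fell in 5 of 17 cases (camera adjusted p = 0.278), with Thy1 at 0.91 (SE 0.17) and decorin, Dcn, at −0.37 (SE 0.07). Growth factors rose in 6 and fell in 2 of 23 cases (0.207), with Igf1 at 0.84 (SE 0.08), Pdgfb at 0.51 (SE 0.06) and Fgf7 at −0.45 (SE 0.07). Axon guidance genes rose in 5 and fell in 5 of 21 cases (0.216), with Robo1 at 1.10 (SE 0.13) and its ligand Slit2 at −0.29 (SE 0.06). Basement membrane genes rose in 6 and fell in 2 of 16 cases (0.0607), with Col18a1 at 0.93 (SE 0.10). Of 11 tumour suppressors 2 rose (0.207), including Cdkn2a at 0.79 (SE 0.16). Macrophage markers rose in 3 and fell in 1 of 20 cases (0.246), the fall being Gpnmb (−1.55, SE 0.25). Endothelial (0.207), mural (0.440), T and NK cell (0.617), B and plasma cell (0.650), mast cell (0.207), keratinocyte (0.440) and mitochondrial genome (0.440) lists had at most 1 called member each.

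In total 15 of 31 lists were called in the bridge, 8 higher and 7 lower. None kept its call with an estimated correlation, and another split of the same 6 libraries called 14 lists. The count of 2795 genes was 1662 without CTL bridge 1, 1678 without Nf1 KO bridge 1, 762 without both muscle-rich libraries (CTL bridge 1 and 3) and 166 when tested against a log2 change of 0.5.

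**Figure D1:**
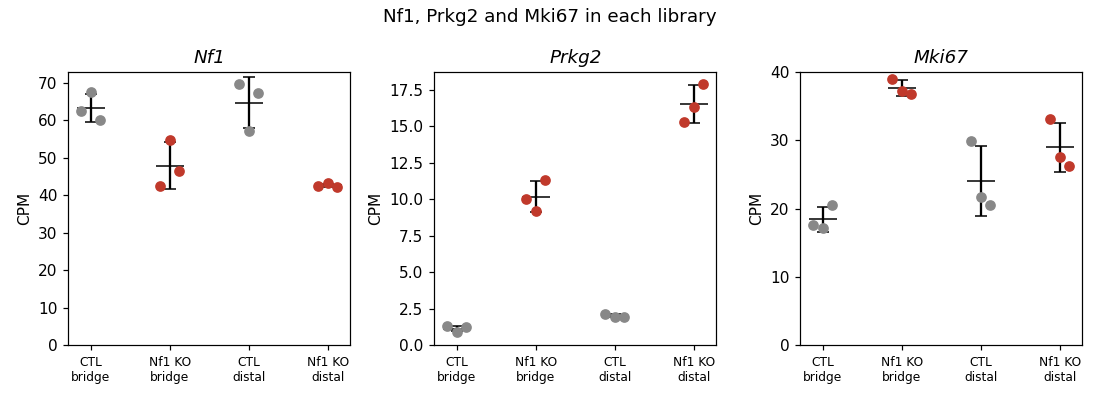
Level in CPM of Nf1, Prkg2 and Mki67 in each of the 12 libraries (points), by group, with bars for the mean and SD of 3 libraries. Nf1 lies lower in every Nf1 KO library of each region, Prkg2 rises from 1.13 to 10.2 CPM in the bridge and from 2.02 to 16.5 CPM in the distal stump, and Mki67 rises in the bridge from 18.4 to 37.6 CPM. In the distal stump Mki67 stands at 24.1 CPM in CTL and 29.0 CPM in Nf1 KO and was not called in the fit of all 12 libraries.

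The same genotype comparison was made in the distal stump. Prkg2 rose from 2.02 ± 0.118 to 16.5 ± 1.30 CPM (3.03, SE 0.14, adjusted p = 7.0e-06) and Corin from 2.81 ± 0.31 to 26.6 ± 1.81 CPM (3.24, SE 0.17, adjusted p = 8.8e-06). Add2 (3.55, SE 0.43), Serinc2 (3.40, SE 0.55), Ajap1 (3.16, SE 0.32), Nwd2 (2.84, SE 0.29), Fhdc1 (2.69, SE 0.26) and the Wnt ligand gene Wnt16 (2.57, SE 0.27) were also among the largest rises. BC035947 (−2.21, SE 0.27) and the chemokine gene Ccl24 (−2.01, SE 0.35) fell. The test called 1562 genes, 854 higher and 708 lower in Nf1 KO, 251 of them changed at least 2-fold.

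RAS/ERK feedback genes rose in 9 of 20 cases and fell in none (10 adjusted over the list alone, camera adjusted p = 9.3e-09, and adjusted p = 0.0642 with an estimated correlation). Spry4 rose by 0.92 (SE 0.10), Spred1 by 0.82 (SE 0.05), Etv1 by 0.72 (SE 0.09) and Dusp6 by 0.58 (SE 0.07). TGF-beta genes rose in 8 and fell in 2 of 21 cases (11 adjusted over the list alone, camera adjusted p = 8.5e-04, and adjusted p = 0.169 with an estimated correlation), with the activin subunit gene Inhba at 1.90 (SE 0.18), Tgfbi at 1.25 (SE 0.08) and Skil at 0.76 (SE 0.05). Matrix genes rose in 13 of 22 cases (17 adjusted over the list alone, camera adjusted p = 1.5e-09, and adjusted p = 0.301 with an estimated correlation). Among them were Col12a1 (1.19, SE 0.13), Col1a1 (0.63, SE 0.10) and Thbs2 (0.58, SE 0.09). Dendritic cell and MHC class II genes rose in 3 of 13 cases (5 adjusted over the list alone, camera adjusted p = 2.3e-04, and adjusted p = 0.484 with an estimated correlation). Flt3 was at 1.53 (SE 0.20). Of the 22 proliferation genes only 3 passed over all genes and 17 adjusted over the list alone (median 0.29, camera adjusted p = 1.0e-07, and adjusted p = 0.380 with an estimated correlation).

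Myelin genes fell in 12 of 20 cases (18 adjusted over the list alone, median −0.63, camera adjusted p = 1.1e-07, and adjusted p = 0.497 with an estimated correlation). They included the galactolipid synthesis genes Ugt8a (−0.93, SE 0.18) and Fa2h (−0.87, SE 0.17), and Cldn19 (−0.73, SE 0.13). Endothelial markers fell in 7 of 14 cases and rose in none (11 adjusted over the list alone, camera adjusted p = 1.0e-07, and adjusted p = 0.255 with an estimated correlation). Cldn5, a tight junction gene of barrier vessels, fell from 66.8 ± 12.0 to 33.6 ± 2.44 CPM (−0.99, SE 0.14), and the junction gene Esam fell by 0.55 on the log2 scale (SE 0.09). Perineurial markers fell in 6 of 11 cases (8 adjusted over the list alone, camera adjusted p = 0.0012, and adjusted p = 0.255 with an estimated correlation). Ntn4 was at −0.89 (SE 0.12), Itgb4 at −0.76 (SE 0.10) and Lypd2 at −0.67 (SE 0.12). Cholesterol synthesis genes fell in 3 of 18 cases (11 adjusted over the list alone, camera adjusted p = 3.3e-06, and adjusted p = 0.497 with an estimated correlation). The neuronal list (0 of 9 called, 0 adjusted over the list alone, camera adjusted p = 0.0203, and adjusted p = 0.484 with an estimated correlation) and the adipocyte list (1 of 12 called, Lpl at −0.56, SE 0.09, 1 adjusted over the list alone, camera adjusted p = 0.0303, and adjusted p = 0.843 with an estimated correlation) were called lower. The neuronal list's adjusted p was 0.0942 without CTL distal 2 and 0.0761 without Nf1 KO distal 1, and the adipocyte list's was 0.232 without CTL distal 3, 0.0963 without Nf1 KO distal 1 and 0.0791 without Nf1 KO distal 3.

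Other named changes in the distal stump lay in lists without a call. The Schwann lineage transcription factor gene Sox8 (chromosome 17, 25565892 to 25570686) rose from 12.4 ± 0.722 to 34.7 ± 2.61 CPM (1.49, SE 0.11, adjusted p = 7.3e-05), and the lipid-binding protein gene Fabp7 rose by 2.19 (SE 0.31). Ncam1 (0.99, SE 0.10), the fractalkine receptor gene Cx3cr1 (1.08, SE 0.16), Hbegf (1.01, SE 0.14), Cxcl14 (1.26, SE 0.10), Robo1 (1.04, SE 0.13) and the tumour suppressors Cdkn2a (0.99, SE 0.16) and Cdkn2b (0.61, SE 0.11) rose. Slit2 (chromosome 5, 47983138 to 48307733) fell from 82.5 ± 1.78 to 44.3 ± 2.77 CPM (−0.90, SE 0.06, adjusted p = 3.7e-05). Fibroblast genes Sfrp2 (−1.39, SE 0.27) and Clec3b (−1.09, SE 0.16) and the interleukin-7 receptor gene Il7r (−1.20, SE 0.20) fell. Lists called numbered 11 of 31, 5 higher and 6 lower, none with an estimated correlation, and other splits of these 6 libraries called up to 13. Under fry the cholesterol synthesis list had an adjusted p of 0.0656 and the adipocyte list 0.322. Nf1 KO distal 1 stood apart, with Acta1 at 598 CPM against 1.59 and 18 in the other Nf1 KO distal libraries, a muscle list mean log2 CPM of 7.08 against 0.366 and 2.52, and 24.5% of its counts in Gm15662. The muscle list was not called (median 2.25, adjusted p = 0.534). The growth factor list's median (−0.04) and mean (0.05), and the mitochondrial list's median (0.08) and its downward test, differ in sign. The gene count was 980 without CTL distal 1, 909 without CTL distal 3, 893 without Nf1 KO distal 2, 939 without Nf1 KO distal 3, 803 when distal libraries alone were fitted and 120 when tested against a log2 change of 0.5.

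The genotype effects of the regions overlapped. Of the genes higher in Nf1 KO, 464 were called in both regions, against 66.7 by chance, and of those lower, 414 against 47.9. They include Prkg2, Corin, Add2, Ajap1, Spry4, Spred1, Skil, Col12a1 and Robo1 among the rises, and BC035947, Ntn4, Lypd2, Cldn19 and Lpl among the falls. Only 5 genes were called in opposite directions. The regions shared no libraries, but their pools are not known to come from different mice, so differences between mice are not excluded as a part of this overlap. Of 3474 genes called in either region, 3035 (87.4%) had the same sign in both. Across all 19189 tested genes, which are not independent replicates, Pearson's r between the log2 fold changes was 0.19 and Spearman's rho 0.38.

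**Figure D2:**
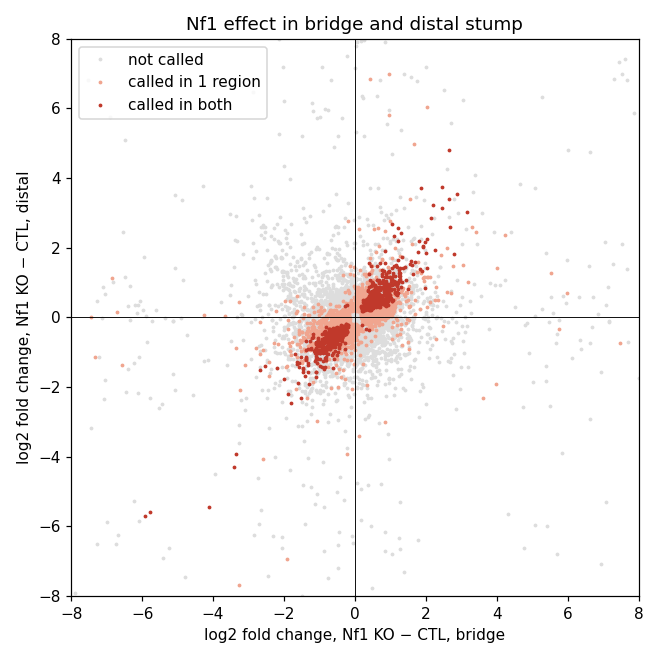
Log2 fold change of Nf1 KO over CTL in the bridge (x axis) and the distal stump (y axis), 1 point per tested gene within the plotted range, coloured by the regions in which it was called. Genes called in both regions lie mostly in the quadrants of equal sign, 464 higher and 414 lower against 5 of opposite direction.

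Whether the genotype effect differed between regions was tested as an interaction of genotype and region. edgeR called 0 of 19189 genes, while 2534 had an unadjusted p under 0.05 and DESeq2 called 447, 204 of them with a positive and 243 with a negative interaction. The smallest adjusted p was 0.0873, so none of the following values passed. They were Rrm2 (interaction log2 change 0.76, SE 0.10), Slit2 (0.61, SE 0.08), Med14 (0.41, SE 0.06), Tgfbi (−0.84, SE 0.11), Itga10 (−1.18, SE 0.16) and D10Jhu81e (−0.56, SE 0.08), each with adjusted p = 0.0873, and Sox8 (−1.02, SE 0.15) and Ahr (0.74, SE 0.11), each with adjusted p = 0.0923. A gene called in only 1 region is therefore not shown to respond differently in the other.

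In control nerves, the bridge was compared with the distal stump to describe how the tissues differ without the mutation. The tight junction gene Cldn1 (chromosome 16, 26356642 to 26371841) was higher in the bridge, 317 ± 20.8 against 129 ± 3.82 CPM (log2 fold change 1.29, SE 0.09, adjusted p = 4.2e-04). The keratin gene Krt15 (2.73, SE 0.32), the hypoxia-induced growth factor gene Vegfa (1.13, SE 0.22) and the collagen gene Col3a1 (1.25, SE 0.15) were also higher. Lower in the bridge were the neurotrophic factor gene Artn (chromosome 4, 117926162 to 117929763), 0.785 ± 0.268 against 3.91 ± 0.36 CPM (−2.29, SE 0.33, adjusted p = 0.0038), the Wnt ligand gene Wnt2b (−1.96, SE 0.20), Shh (−1.52, SE 0.22) and the monocyte chemokine gene Ccl2 (−1.47, SE 0.19). The test called 1891 genes, 988 higher and 903 lower in the bridge, 355 of them at least 2-fold.

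Repair Schwann cell genes were lower in the CTL bridge in 14 of 18 cases (16 adjusted over the list alone, median −1.17, camera adjusted p = 7.7e-13, and adjusted p = 0.235 with an estimated correlation). Gap43 was at −1.16 (SE 0.17) and Ngfr at −1.13 (SE 0.18). Chemokines and cytokines were lower in 9 of 26 cases (14 adjusted over the list alone, camera adjusted p = 3.9e-07, and adjusted p = 0.235 with an estimated correlation). Ccl7 was at −0.93 (SE 0.17). Macrophage markers were lower in 8 of 20 cases (10 adjusted over the list alone, camera adjusted p = 1.1e-05, and adjusted p = 0.317 with an estimated correlation). The lipid carrier gene Apoe was among them (−0.83, SE 0.15). Proliferation genes were lower in 3 of 22 cases (15 adjusted over the list alone, median −0.32, camera adjusted p = 3.5e-07, and adjusted p = 0.292 with an estimated correlation). Higher in the bridge were 13 of 18 cholesterol synthesis genes (16 adjusted over the list alone, camera adjusted p = 5.0e-10, and adjusted p = 0.281 with an estimated correlation). Among them were Idi1 (0.89, SE 0.16), Cyp51 (0.88, SE 0.14) and Hmgcs1 (0.80, SE 0.15). Of 22 matrix genes 15 were higher and 1 lower (19 adjusted over the list alone, camera adjusted p = 4.4e-10, and adjusted p = 0.241 with an estimated correlation). Col12a1 was at 0.95 (SE 0.13). Myelin genes were higher in 3 of 20 cases (11 adjusted over the list alone, camera adjusted p = 3.4e-04, and adjusted p = 0.659 with an estimated correlation). Ncmap was at 1.03 (SE 0.18).

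Vessel and stromal lists were also higher in the CTL bridge. Fibroblast markers were higher in 8 and lower in 1 of 17 cases (11 adjusted over the list alone, camera adjusted p = 1.8e-04, and adjusted p = 0.251 with an estimated correlation). Cd34 was at 0.79 (SE 0.16) and Dcn at 0.48 (SE 0.07). Endothelial markers were higher in 3 of 14 cases (6 adjusted over the list alone, camera adjusted p = 1.8e-04, and adjusted p = 0.317 with an estimated correlation). Emcn was at 0.48 (SE 0.08). Mural cell markers were higher in 5 of 12 cases (7 adjusted over the list alone, camera adjusted p = 0.0073, and adjusted p = 0.459 with an estimated correlation). Among them were the channel genes Kcnj8 (1.31, SE 0.20) and Abcc9 (1.11, SE 0.20) and Rgs5 (0.95, SE 0.10). The TGF-beta list (7 higher, 1 lower of 21, 10 adjusted over the list alone, camera adjusted p = 0.0073, and adjusted p = 0.235 with an estimated correlation) included Ltbp1 (0.80, SE 0.14). The axon guidance list (6 higher, 2 lower of 21, 12 adjusted over the list alone, camera adjusted p = 0.0179, and adjusted p = 0.317 with an estimated correlation) included Epha4 (0.92, SE 0.10) higher and Slit2 (−0.48, SE 0.06) lower. The growth factor list (6 higher, 2 lower of 23, 8 adjusted over the list alone, camera adjusted p = 0.0406, and adjusted p = 0.235 with an estimated correlation) included Fgf1 (0.76, SE 0.13) and Igf1 (0.59, SE 0.08). Of 3 measured keratinocyte genes 1 was higher (2 adjusted over the list alone, camera adjusted p = 0.0073, and adjusted p = 0.235 with an estimated correlation), and the list's p was 0.204 when no gene was filtered out. Without CTL bridge 2 the axon guidance list had a camera adjusted p of 0.0824 and the growth factor list 0.0557, and the latter had 0.0591 without CTL bridge 1 and 0.0568 without CTL distal 3.

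Skeletal muscle transcripts stood beside all of these differences. Acta1 was at 1220.0 ± 818 CPM in the CTL bridge and 58.5 ± 61.1 CPM in the CTL distal stump. The muscle list had 1 of 16 members called and 15 adjusted over the list alone (median 4.69, camera adjusted p = 3.5e-07, and adjusted p = 0.365 with an estimated correlation). Its mean log2 CPM was 8.74, 6.09 and 8.42 in CTL bridge libraries 1 to 3 and 0.539, 3.20 and 4.11 in CTL distal libraries 1 to 3. With that mean as a covariate only 59 genes were called, and the endothelial (camera adjusted p 0.375), mural (0.329), axon guidance (0.101) and growth factor (0.134) lists lost their calls. Without the muscle-rich libraries CTL bridge 1 and 3 the count was 527, and the growth factor list's p was 0.0680. The myelin list had an adjusted p of 0.137 under fry. The count was 704 without CTL bridge 1, 1057 without CTL bridge 2, 694 without CTL distal 1, 835 without CTL distal 2, 713 when CTL libraries alone were fitted and 61 when tested against a log2 change of 0.5. In all 15 lists were called, 11 higher and 4 lower in the bridge, none with an estimated correlation, and other splits of these libraries called up to 17. The perineurial list (median −0.12, mean 0.27) and the tumour suppressor list (median 0.01, mean −0.09) differ in sign between summaries and were not called.

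The corresponding comparison in Nf1 KO nerves gave 2914 genes, 1492 higher and 1422 lower in the bridge, 514 of them at least 2-fold. The Notch-like ligand gene Dlk1 was higher in the bridge, 20.8 ± 7.85 against 0.826 ± 0.731 CPM (4.65, SE 0.86, adjusted p = 0.0058), as was the transcription factor gene Klf14 (3.39, SE 0.49). Olig1 (−3.49, SE 0.47), the prolactin family gene Prl2c2 (−3.63, SE 0.64), the apolipoprotein gene Apoc4 (−3.15, SE 0.39), the Wnt inhibitor gene Wif1 (−2.55, SE 0.38) and Inmt (−2.51, SE 0.15, adjusted p = 1.7e-04) were lower. Of the calls, 536 were higher in the bridge in both genotypes, against 76.8 by chance, 495 were lower in both, against 66.9, and 10 had opposite directions.

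Matrix, vessel and lipid synthesis genes were higher in the Nf1 KO bridge. Matrix genes were higher in 16 and lower in 1 of 22 cases (17 adjusted over the list alone, camera adjusted p = 5.4e-10, and adjusted p = 0.234 with an estimated correlation). Postn was at 1.38 (SE 0.16), the cross-linking enzyme gene Loxl1 at 1.31 (SE 0.14) and Col14a1 at 1.30 (SE 0.12). Cholesterol synthesis genes were higher in 14 of 18 cases (17 adjusted over the list alone, camera adjusted p = 5.7e-10, and adjusted p = 0.264 with an estimated correlation). Idi1 was at 1.08 (SE 0.16). Endothelial markers were higher in 11 of 14 cases (11 adjusted over the list alone, camera adjusted p = 3.0e-08, and adjusted p = 0.234 with an estimated correlation). Among them were Plvap (1.21, SE 0.14) and the VEGF receptor gene Kdr (1.09, SE 0.12). Mural markers were higher in 4 of 12 cases (8 adjusted over the list alone, camera adjusted p = 0.0129, and adjusted p = 0.504 with an estimated correlation). Kcnj8 was at 1.47 (SE 0.21). Fibroblast markers were higher in 7 and lower in 2 of 17 cases (15 adjusted over the list alone, camera adjusted p = 1.7e-04, and adjusted p = 0.234 with an estimated correlation). Fbln1 was at 1.25 (SE 0.15) and Mfap5 at 1.16 (SE 0.15).

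Proliferation genes were higher in the Nf1 KO bridge in 8 of 22 cases and lower in none (10 adjusted over the list alone, median 0.30, camera adjusted p = 2.7e-04, and adjusted p = 0.447 with an estimated correlation). Ccnb2 was at 0.60 (SE 0.11) and Ccna2 at 0.42 (SE 0.08). Axon guidance genes (9 higher, 2 lower of 21, 12 adjusted over the list alone, camera adjusted p = 3.2e-04, and adjusted p = 0.234 with an estimated correlation) included Ephb2 (0.88, SE 0.09) and Nrp1 (0.79, SE 0.07). Growth factors (9 higher, 1 lower of 23, 11 adjusted over the list alone, camera adjusted p = 4.2e-04, and adjusted p = 0.0907 with an estimated correlation) included Igf1 (0.95, SE 0.08) higher and Pdgfa (−0.55, SE 0.08) lower. TGF-beta genes (7 higher, 1 lower of 21, 10 adjusted over the list alone, camera adjusted p = 0.0171, and adjusted p = 0.234 with an estimated correlation) included Ltbp4 (1.06, SE 0.13) and Tgfbr2 (0.62, SE 0.07). Interferon-stimulated genes (5 higher of 20, 6 adjusted over the list alone, camera adjusted p = 0.0060, and adjusted p = 0.658 with an estimated correlation) included Isg15 (0.58, SE 0.12). The muscle list, with no called member (0 adjusted over the list alone), had a median of −0.01 and a test pointing up (camera adjusted p = 0.0345, and adjusted p = 0.755 with an estimated correlation).

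Repair Schwann cell genes were lower in the Nf1 KO bridge in 14 of 18 cases and higher in 1 (15 adjusted over the list alone, camera adjusted p = 8.8e-09, and adjusted p = 0.234 with an estimated correlation). Ngfr was at −1.33 (SE 0.19) and Gap43 at −1.26 (SE 0.17). Schwann lineage markers were lower in 6 of 12 cases (6 adjusted over the list alone, camera adjusted p = 0.0017, and adjusted p = 0.264 with an estimated correlation). Among them were Cdh19 (−0.65, SE 0.08) and the neuregulin receptor gene Erbb3 (−0.63, SE 0.09). Macrophage markers were lower in 8 of 20 cases (12 adjusted over the list alone, camera adjusted p = 5.3e-05, and adjusted p = 0.399 with an estimated correlation). Among them were Gpnmb (−1.81, SE 0.25), Apoe (−1.38, SE 0.15) and Trem2 (−1.04, SE 0.17). Adipocyte genes were lower in 7 of 12 cases (9 adjusted over the list alone, camera adjusted p = 1.2e-04, and adjusted p = 0.447 with an estimated correlation). Retn was at −1.63 (SE 0.28) and Cfd at −1.57 (SE 0.34). Chemokines and cytokines were lower in 6 and higher in 1 of 26 cases (9 adjusted over the list alone, camera adjusted p = 0.0066, and adjusted p = 0.453 with an estimated correlation). Ccl2 was at −1.57 (SE 0.19), Spp1 at −1.08 (SE 0.15) and Cxcl12 at 0.84 (SE 0.14).

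In all 16 lists were called in Nf1 KO, 11 higher and 5 lower in the bridge, none with an estimated correlation, and another split of these libraries called 13. The muscle list's p was 0.135 without Nf1 KO bridge 1, 0.0559 without Nf1 KO bridge 3, 0.519 without Nf1 KO distal 2 and 0.103 without Nf1 KO distal 3. The chemokine and TGF-beta lists had 0.0512 and 0.0598 without Nf1 KO bridge 2, and the interferon list 0.0669 without Nf1 KO bridge 3. Under fry the interferon list had 0.150 and the muscle list 0.394. Acta1 stood at 316 ± 165 CPM in the Nf1 KO bridge and 206 ± 340 in the distal stump. The gene count was 1844 without Nf1 KO bridge 1, 1896 without Nf1 KO distal 2, 1622 without Nf1 KO distal 3, 1854 with same-numbered libraries fitted as pairs and 285 when tested against a log2 change of 0.5. The neutrophil, T and NK cell, RAS/ERK feedback and tumour suppressor lists, none called by camera, differ in sign between their median and their mean or test.

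**Figure D3:**
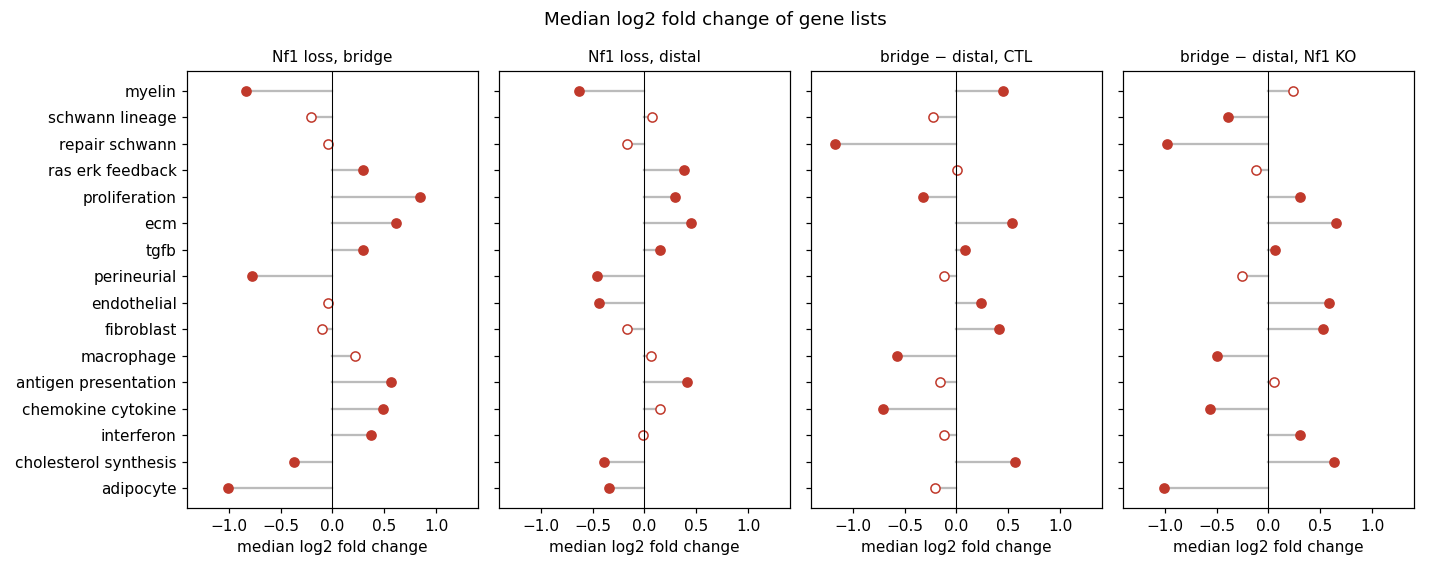
Median log2 fold change of 16 gene lists (y axis) in the genotype comparison of each region and the region comparison of each genotype (x axis, log2 units), with filled symbols where camera's adjusted p with a preset correlation was under 0.05. The proliferation list lies at 0.84 for the bridge genotype effect and at 0.29 for the distal one, and the repair Schwann cell list at −1.17 in CTL and −0.98 in Nf1 KO for the region comparison.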

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

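The list tests of the interaction were added after the data were seen, and the tests of a chromosome stretch around Nf1 were chosen only after the result was seen.

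The genotype effect of 8 lists differed between regions by camera with a preset correlation, although no single gene did in edgeR (2534 genes at an unadjusted p under 0.05, 447 called by DESeq2). Proliferation genes changed more in the bridge (median interaction log2 change 0.55, adjusted p = 1.5e-16, and adjusted p = 0.429 with an estimated correlation). Interferon-stimulated genes did too (0.45, adjusted p = 5.6e-04, and 0.833 with an estimated correlation), while endothelial markers (0.31, 5.6e-04, and 0.648) changed less in the bridge (median −0.05) than in the distal stump, where they fell (−0.44). The interaction was negative for adipocyte genes (−0.73, 5.6e-04, and 0.809), Schwann lineage markers (−0.26, 0.0018, and 0.648), skeletal muscle genes (−4.85, 0.0045, and 0.895), myelin genes (−0.24, 0.0127, and 0.895) and perineurial markers (−0.32, 0.0297, and 0.648). The distal part of the muscle difference rests on Nf1 KO distal 1, where the mean log2 CPM of the list was 7.08, against 0.366 and 2.52 in the other Nf1 KO distal libraries and 0.539 to 4.11 in CTL. With the genotype labels regrouped within each region, 70 of 100 splits called as many lists and the highest other called 20. For single genes the real count is 0, so 100 of 100 splits give as many by construction, which says nothing about chance. The highest other split called 210 genes. Some of these splits keep the real genotype groups of 1 region and regroup the other, so they hold genotype effects themselves and decide nothing about chance.

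For the proliferation list, 3 technical explanations were tested. With the muscle transcripts as a covariate the median was 0.53, with Y-linked transcripts 0.55, and without CTL bridge 1, the lowest of the 6 values with a bridge library left out, 0.51. The values with the muscle covariate and with a bridge library left out argue against those explanations as the whole cause. The Y-linked value does not decide about the sex of the mice. Y-linked genes were lower in Nf1 KO in both regions, and a shared difference cancels in the interaction. Of 100 splits of the genotype labels, 15 gave a list median as far from 0 and the highest other was 1.04. Some of these splits keep the real genotype groups of 1 region, so this does not decide whether chance can be excluded. A stronger cell cycle response of the bridge to loss of Nf1 stays open.

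The splits of each pair of groups are 10 with the real one, too few for a share under 0.05. Real gene counts of 2795, 1562, 1891 and 2914 (genotype in bridge and distal stump, region in CTL and Nf1 KO) stood against highest others of 1, 1, 0 and 0, so 1 of 10 splits gave as many in each. Every other split puts libraries of both real groups on each side. A real difference of any cause then widens the spread and lowers the gene calls, so this gap does not show what caused the difference. Real list counts of 15, 11, 15 and 16 stood against highest others of 14, 13, 17 and 13, and 1, 4, 2 and 1 of 10 splits gave as many.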

How the results depend on the processing

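The covariates, the joint removal of CTL bridge 1 and 3, protein-coding genes alone, repeated genes counted once, the limit of 500 bases and the nested pairs were chosen after the data were seen; the others were planned.

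Counts of called genes stayed within 1.5 times the reported one under RLE and upper-quartile factors, limma-voom with and without weights, both filters and the robust fit. DESeq2 did so for 4 comparisons (3466, 2267, 2727 and 3611 genes), but called 447 genes for the interaction; the cause was not tested. The test against a log2 change of 0.5 asks for a larger effect by construction and called 166, 120, 61 and 285 genes. Fitting only the compared groups, which leaves fewer libraries to estimate the spread, gave 803 genes for genotype in the distal stump, 713 for region in CTL, and Nf1 at −0.41 (adjusted p = 0.0541) in the bridge. With CTL bridge 1 and 3 left out, which leaves a lone CTL bridge library assumed to vary like the other groups, genotype in the bridge gave 762 genes and region in CTL 527. The muscle covariate gave 59 genes for region in CTL and 11 for the interaction; it follows region closely in CTL, and the cause of the 11 was not tested. Genes of at least 500 bases gave 2997, 1685, 2129 and 3079 calls and 0 for the interaction.

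Leaving out each library in turn, which lowers the number of samples, gave 1662 to 2253 genes for genotype in the bridge, 893 to 1322 in the distal stump, 694 to 1926 for region in CTL, 1622 to 2958 in Nf1 KO and 0 to 0 for the interaction. Nf1 ranged from −0.51 to −0.32 in the bridge, where 4 of 6 lost the call, and from −0.68 to −0.54 in the distal stump, where none did (largest adjusted p = 0.0236). Lists called numbered 13 to 18, 11 to 15, 14 to 19 and 14 to 17. With an estimated correlation 0 lists were called in all 4 comparisons, and fry called 14, 9, 14 and 15. The former test takes the correlation of the members from the data in place of the preset 0.01, and why no list passed it was not tested. Under fry the calls lost were cholesterol synthesis (adjusted p = 0.105), interferon (0.105), erythroid (0.0822) and muscle (0.318) for genotype in the bridge. Cholesterol synthesis (0.0656) and adipocyte (0.322) were lost in the distal stump, myelin (0.137) for region in CTL, and interferon (0.150) and muscle (0.394) in Nf1 KO. For genotype in the bridge and region in Nf1 KO, fry also called lists that camera did not. With the Y-linked covariate, camera lost erythroid (0.0596) and muscle (0.322) for genotype in the bridge and muscle (0.142) for region in Nf1 KO. The muscle covariate is the mean of the muscle list itself, so under it that list loses its calls by construction. Its values were 0.922 for genotype in the bridge, 0.530 for region in CTL and 0.637 for region in Nf1 KO. For region in CTL the endothelial (0.375), mural (0.329), growth factor (0.134) and axon guidance (0.101) lists also lost their calls with the muscle covariate. The causes of the other losses were not tested.

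The labels used here do not say whether same-numbered bridge and distal pools came from the same mice, and the numbers were not taken as pairs because, over all tested genes, not every correlation was over 0.1. Deviations of same-numbered libraries correlated at −0.0036 to 0.0811 for genotype in the bridge, −0.064 to −0.00997 in the distal stump, 0.00682 to 0.0298 for region in CTL and 0.034 to 0.139 in Nf1 KO over all tested genes, and libraries did not correlate best with their own number throughout. Over 11176 abundant genes, looked at first, every pair of Nf1 KO was over 0.1 (0.182 to 0.318), so there the choice of genes decides, while CTL gave −0.108 to −0.0144. Some values go together by number: Nlrp1c-ps stood at 1.38, 0.524 and 2.49 CPM in CTL bridge 1 to 3 and 1.68, 0.531 and 2.19 in CTL distal 1 to 3, and the Y-linked mean was lowest in library 2 of every group (4.63, 3.36, 4.80 and 3.32). Shared mice therefore stay open. The replicate block gave 2464, 1284, 1497 and 2463 genes and 0 for the interaction, 15, 13, 15 and 16 lists, and Nf1 at −0.40 (adjusted p = 0.0419) and −0.60 (0.0153). Pairs nested in genotype gave 853 genes for region in CTL and 1854 in Nf1 KO; the cause was not tested.

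Of 367 called values of named genes, 121 lost the call in at least 1 alternative and 0 reversed, over 3303 alternative values of which 478 were past the threshold no longer. Depth limits weak genes, since a library resolves 0.0770 to 0.159 CPM. Simulated changes of log2 0.5 were recovered in 23.5% of 68 genes for genotype in the bridge. Those genes were drawn from all tested genes, and the part of depth in this share was not tested.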

Other observations

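Families of related genes, some of whose members are also in the fixed lists, were grouped after the data were seen, the alternatives were not run on them, and the tests of a chromosome stretch around Nf1 were chosen after the result was seen; the test on Y-linked genes was not.

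The collagen family includes the collagens of the matrix and basement membrane lists, so its result partly restates theirs. In the Nf1 KO bridge 19 of 44 collagens rose and 4 fell (camera adjusted p = 2.2e-04, and adjusted p = 0.250 with an estimated correlation), with, outside those lists, Col8a1 at 1.13 (SE 0.09) and the fibril gene Col11a1 at 0.87 (SE 0.08). In the distal stump 18 rose and none fell (1.2e-06, and 0.202 with an estimated correlation), Col11a1 by 1.00 (SE 0.07). Replication-linked histone genes rose in 29 of 68 cases in the bridge and 15 in the distal stump, with 1 fall in each (1.9e-13 and 9.1e-12, and 0.250 and 0.322 with an estimated correlation), but they are short and nearly identical to each other. The histone gene Hist1h4m was nearly lost in Nf1 KO, from 188 to 3.03 CPM in the bridge (−5.92, edgeR adjusted p = 0.0182). In the distal stump it went from 214 to 4.24 CPM (−5.71, edgeR adjusted p = 0.0292).

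Claudins fell in 5 of 15 cases and rose in 1 in each region (0.0146 and 0.0232, and 0.250 and 0.202 with an estimated correlation). Cldn5 of barrier vessels fell (log2 change −1.10, SE 0.14 in the bridge and −0.99, SE 0.14 in the distal stump), while Cldn15 rose by 0.97 (SE 0.16) and 0.86 (SE 0.15). Semaphorins, which guide axons, fell in 5 of 20 cases in the distal stump (5.7e-04, and 0.180 with an estimated correlation), Sema6d at −0.56 (SE 0.09) and Sema3d at −0.49 (SE 0.11). In the bridge 5 also fell and 1 rose (0.0643, not called), with a median of −0.19 against −0.20. Between regions, complement genes were lower in the bridge in 5 of 15 cases in CTL and 6 in Nf1 KO (0.0072 and 0.0099, and 0.368 and 0.482 with an estimated correlation), C3 at −1.51 (SE 0.30) and −1.10 (SE 0.29). ADAMTS and matrix metalloproteinase genes were higher in the Nf1 KO bridge in 14 of 36 cases and lower in 2 (2.5e-04, and 0.378 with an estimated correlation), Adamts12 by 1.02 (SE 0.10), and in CTL in 7 cases and lower in 3 (0.0438, and 0.368 with an estimated correlation).

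Y-linked genes were lower in Nf1 KO, with a mean log2 CPM of 5.16 in 6 CTL and 4.25 in 6 Nf1 KO libraries. Pools that mix male and female mice may account for this. Over 12 libraries the Y-linked mean fell where 4 genes escaping X inactivation rose (Pearson r = −0.90, permutation p = 8e-05). Spearman's rho was −0.95 (permutation p = 1e-05, the smallest 100000 resamples can give). Both permutations treat the 12 libraries as independent. If same-numbered bridge and distal pools share mice, which stays open, these p-values are too small. The coefficient was −0.90 without Nf1 KO distal 2 and Nf1 KO bridge 2, −0.86 within Nf1 KO and −0.99 within CTL. The sex of the mice in each pool was not tested by other means.

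Some transcripts were nearly lost or gained in Nf1 KO in both regions. Gm8797 went from 116 to 2.12 CPM in the bridge and from 135 to 2.79 in the distal stump (−5.79 and −5.60), and Gm20474 from 6.74 to 0.384 and from 11.1 to 0.248 CPM. These lie on chromosomes 3 and 12. Nlrp1b went from 3.27 to 7.83 and from 3.67 to 8.38 CPM, and Nlrp1c-ps from 1.47 to 9.57 and from 1.46 to 8.97 CPM, the latter on chromosome 11 (71242430 to 71285232). A stretch of another strain's chromosome 11 carried with the floxed allele is a candidate explanation for the Nlrp1 genes, but not for Gm8797 and Gm20474. Within 10 Mb of Nf1, 25 of 382 genes (6.54%) were called in both regions against 853 of 18807 elsewhere (4.54%). The odds ratio was 1.47 (Fisher's exact p = 0.0814), which leaves the stretch undecided for the Nlrp1 genes. The 25 include Nf1 itself and the genes that prompted the test, Nlrp1a, Nlrp1b and Nlrp1c-ps. The odds ratio therefore partly restates the observation it was meant to explain. Of 18 genes with a log2 change above 2 in size in both regions, 16 have a position in the annotation and 2 lie within 10 Mb of Nf1. This argues against that stretch as the place of most of them. The 2 are Nlrp1c-ps and a lost transcript, Gm11425 (−4.09 in the bridge and −8.28 in the distal stump). For Gm11425 the stretch is a candidate too. Differences of strain background elsewhere in the genome, and an effect of Nf1 loss, stay open.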
